A study of Homo sapiens with 12 samples.

How the data were processed

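SON TSA-seq pulldown and input DNA, sheared to a mean of 250 bp, was sequenced from IMR90 cells grown in 3% oxygen, per the labels' protocols. The groups were DMSO SON, Nutlin SON and no primary antibody, each with 2 replicates of pulldown and of input, taken from the sample titles. Nothing in the labels says whether replicates were separate cultures, so p-values may measure technical spread alone. The submitters' processing notes name Bowtie2, SAMtools 1.1, Picard, DiffBind, bedtools and build hg19, with no role, order or options. Normalisation, the handling of input reads and the filters are not given in the sources used here.

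The authors deposited 36 tables of DiffBind results, 9 for each window size of 25, 50, 100 and 500 kb, with the 9 tables starting at steps of 2.5, 5, 10 and 50 kb. Each deposited table gives log2 read concentrations per window as a mean and for DMSO and Nutlin, a log2 fold and the authors' p-value and FDR. The deposited log2 fold equals DMSO minus Nutlin within 0.01, so its sign was turned here and a positive value means more signal with Nutlin. In the median table of 100 kb windows, 61.5% of 30924 windows sat at one lowest value in both conditions (-0.08 in DMSO and -0.15 with Nutlin), so levels there are unknown. Dividing the smallest FDR by its p-value gives an approximate lower bound on the number of windows the authors adjusted over. It was 11751 in the median table at 100 kb and 4286 of 61882 at 50 kb, with a range from 2933 to 23273 over the 50 kb tables. The 50 kb table with 2933 had 4294 windows with an FDR below 1, so more were adjusted over there. Counts past an FDR are therefore not comparable between window sizes. No value per library was analysed here, depth is unknown, and no column of per-sample values was left unused (0 columns).

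The authors also deposited merged gained regions and gene lists at 6 FDR thresholds from 0.1 to 0.00001, a list of 1694 p53 targets and its 2 subsets. Merging all gained windows of the 27 tables of 25, 50 and 100 kb gave back 540 of the 548 regions at FDR 0.01, start and end equal. At FDR 0.1 the authors' regions numbered 689, while this merge gave 3378, and 793 without windows at the lowest DMSO value. The subset lists equal the targets in the gained list at FDR 0.01 and those outside the list at FDR 0.1, except for 12 genes with "orf" in their symbol.

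Gene symbols were matched by name or unambiguous older name to RefSeq genes of GRCh38.p14, used for names, chromosome and gene order alone. Of the targets 99.4% and of the gained genes at FDR 0.01 96.8% matched. The background was 19970 protein-coding genes; which genes the authors could have listed is not given in the sources used here. As the lists carry no positions and hg19 gene positions were not used here, no fold per gene could be computed. The comparison of mean fold between p53 targets or fixed lists and other genes, and of level and length between gained and other targets, was replaced by list membership. Membership was tested with Fisher's exact test, and with all shifts of the labels along the circular gene order by at least 50 genes. Targets were also replaced by random genes at most 5, 20 or 50 places away, 10000 times. These draws could return the target itself or another target. All tests were two-sided, intervals are at 95%, and families of lists or chromosomes were adjusted after Benjamini and Hochberg.

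Genes were assigned to regions per chromosome, where the listed genes fell into as many runs in the gene order as there were regions, runs being parted by at least 2 unlisted protein-coding genes. A looser rule, which let up to 20 unlisted genes part runs and joined regions at most 100 kb apart, was tried afterwards, to place genes on chromosome 2, once the loci above the level trend that had genes were seen to hold targets. Under the strict rule 0 of 70 genes placed at both FDR 0.00001 and 0.0001 and 0 of 67 at both 0.0001 and 0.001 changed region. Under the looser rule 57 of 183 genes did at the latter pair. On simulated regions 100% of the genes that the strict rule placed were right, and for the looser rule 95.1% with 42 regions drawn per simulation and 74.8% with 228. The strict rule gave genes to fewer regions, 89.4% with 42 drawn and 27.0% with 228, against 98.5% and 68.7% for the looser rule. The strict rule was kept. The value of a region is the mean over the 9 tables of the 100 kb window that overlaps it most, the one nearest to its centre where several lie inside. For the longest regions the mean over all measured windows inside is given instead. Genes to name were to be the 25 targets with the largest fold; without folds per gene, all targets that could be placed in a region of the strictest list were named with the rise of their region, an adaptation made after the data were seen, along with members of fixed lists in gained regions. Regions named are the 5 longest at FDR 0.01.

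The level trend was taken as the median change in 50 bins of mean level, and the error of each window from its change and p-value, which is approximate. Windows whose change was no larger than its error got the median error of their level instead, which can call noisy windows. In simulated 100 kb windows with such a trend and 200 windows raised past it, the step recovered 8.0% of windows raised by 0.3 log2 units, 28.5% at 0.5 and 66.5% at 1, with 0, 0 and 2 false calls. Without it, 202 to 250 windows that only followed the simulated trend were also called gained. Those calls are false only if the trend itself is not a real change, which is not known. With target labels shifted at random, Fisher's exact test passed 0.05 in 12.5% of 200 simulated cases and the shift test in 4.0%. The shift test passed in 98.0% when 60 targets were moved into gained regions. Alternatives covered FDR thresholds, window sizes, filters, trend removal, the centre of the change, gene blocks, chromosomes and the assignment rule. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.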

Results

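Chromatin contact with nuclear speckles was measured by SON TSA-seq in IMR90 cells, an established line of human lung fibroblasts. In TSA-seq (tyramide signal amplification sequencing), an antibody-bound peroxidase labels DNA near its target with biotin, so that pulled-down DNA is richer the closer a locus lies to the target. SON is a scaffold protein of nuclear speckles, bodies rich in splicing factors. Cells received Nutlin-3a, which blocks the binding of MDM2 to p53 and so stabilises p53, at 5 µM for 6 hours, or DMSO. The series holds 12 libraries, with 2 replicates each of pulldown and input for DMSO SON, Nutlin SON and a control without primary antibody. The authors' deposited tables compare the 2 Nutlin with the 2 DMSO pulldown libraries as group values, so the spread between replicates enters only through the authors' own p-values. Window levels, changes and FDRs given here come from the authors' deposited tables unless a recomputed FDR is named. Read depth per library is unknown here, and the control without primary antibody was not analysed here.

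The first question was where SON signal changed when p53 was activated. In the authors' deposited tables of 100 kb windows, a median of 260 windows per table rose with Nutlin at FDR under 0.01, and 5 fell. Over the 9 tables, which tile the genome at shifted starts, the counts ranged from 234 to 273 and from 4 to 7. A median of 2 of the gained and 2 of the lost windows had a condition at the lowest value, where levels are unknown. At an unadjusted threshold of 0.05 the medians were 2864, of which 1800 had a condition at the lowest value, and 435, of which 348 had. The median rise of the gained windows was 0.37 log2 units, or 1.29-fold, and the central range from the 5th to the 95th percentile ran from 0.30 to 0.56. Gained windows were already rich in SON signal in DMSO, with a median level of 11.94 against 9.23 for all windows measured in both conditions. In the fourth and seventh deciles of mean level, medians of 0 windows were gained and 0 lost. The change varied more at low level, with a 10th to 90th percentile of -1.19 to 0.46 in the fourth decile and 0.10 to 0.37 in the highest. Whether 100 kb windows of low level could have passed was not tested, though FDRs below 1 reached down to a mean level of 0.97 in the median table. In 25 kb windows the lowest mean level with an FDR below 1 was 9.16. In 50 kb windows it was 9.75 (1.77 to 10.16 over the tables). Windows below these levels could not pass. The link of gain with high level may therefore partly reflect which windows could be called. The direction depends on where the scale between conditions puts 0. With the changes centred on the median of all measured windows and FDR recomputed, 324 windows were gained and 4 lost, and centred on the highest decile of SON level, 4 were gained and 24 lost. That decile held most of the gained windows, so the latter centre removes most of them by construction. Tables that share a window size reuse the same reads, so ranges over tables show the effect of window placement and not replicate error.

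The change differed with the level of SON signal. In the authors' deposited tables, among 100 kb windows in the highest decile of the mean level of both conditions, the median change was 0.25 and 97.9% of windows were higher with Nutlin. This decile held 213 of the gained windows in the median table. In the fourth decile the median change was -0.38 and 27.4% of windows were higher. The lowest decile had a median of 0.45 with a wide spread (10th to 90th percentile -1.86 to 3.02). Deciles of the mean level were chosen after the data were seen, and deciles of the DMSO level alone gave 0.24 in the highest, -0.38 in the fourth and 1.36 in the lowest. The rank correlation of the change with the DMSO level was 0.018 over all measured windows and 0.50 over the upper 50% by mean level, across windows that are not independent replicates. After the median change at each level was subtracted, a median of 8 windows per table lay above the trend and 4 below it at a recomputed FDR under 0.01, against 275 gained and 3 lost before with FDR recomputed over the same windows, in an approximate test chosen after the data were seen. On simulated windows that test recovered 8.0% of rises of 0.3 and 28.5% of rises of 0.5.

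**Figure D1:**
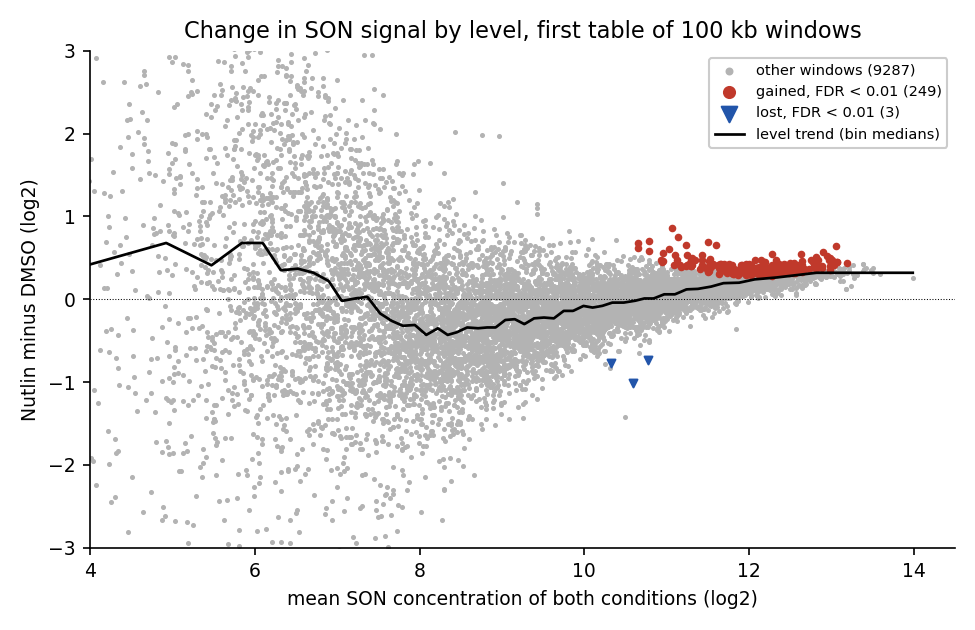
Change in SON signal (Nutlin minus DMSO, log2) against the mean level of both conditions (log2) for 100 kb windows of the first table; red points are the 249 windows gained and blue triangles the 3 lost at FDR under 0.01, and the black line joins the median change in bins of level. Gained windows lie at high levels, where the black line is above 0; 324 of the 9539 measured windows lie outside the axes.

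The authors' merged gained regions at FDR 0.01 numbered 548 and covered 69.8 Mb, with a median length of 80 kb. Chromosome 19 held 104 of them, chromosome 17 held 74, chromosome 1 held 51, chromosome 11 held 45 and chromosome 18 held 0. The longest spanned 1675 kb on chromosome 9 (138800001 to 140475000, hg19). Over the 100 kb windows inside it, the authors' deposited tables gave a mean rise of 0.42 log2 units, with single windows from 0.30 to 0.51. The next were 1080 kb on chromosome 8 (144250001 to 145330000), with a mean of 0.41 (0.28 to 0.78), and 845 kb on chromosome 11 (64280001 to 65125000), with 0.32 (0.23 to 0.40). Then came 780 kb on chromosome 2 (241200001 to 241980000), with 0.61 (0.37 to 0.84), and 670 kb on chromosome 19 (42300001 to 42970000), with 0.35 (0.21 to 0.53). The central windows were also set against the median change at their SON level. On chromosomes 9 and 8 they rose by 0.48 and 0.38, against 0.31 and 0.28. On chromosomes 11 and 19 they rose by 0.30 and 0.29, against 0.29 and 0.25, and on chromosome 2 by 0.60 against 0.04.

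At the strictest deposited threshold, FDR 0.00001, the authors listed 42 regions and 212 genes, of which 39 are on their list of p53 targets in IMR90 cells. In the authors' deposited tables the rise over these regions ranged from 0.35 to 0.90 log2 units, or 1.28-fold to 1.86-fold. Genes could be placed in 30 of the regions by their order, and 28 of the 39 targets fell there. The other 12 regions hold 11 of the targets in places not settled here. Among them, 3 regions on chromosome 2 rose by 0.72 (241220001 to 241500000), 0.55 (241500001 to 241600000) and 0.76 (241610001 to 241780000), and GPC1, the listed target of that chromosome, lies in one of these. A 420 kb region on chromosome 3 (48360001 to 48780000) rose by 0.57, and 9 targets of that chromosome, PLXNB1 and COL7A1 among them, lie in this or the other two regions there (0.50 and 0.41). The largest rise, 0.90 (range 0.83 to 0.94 over 9 tables), lay on chromosome 17 (72760001 to 72960000), in the region of the targets NAT9 and FDXR. FDXR encodes ferredoxin reductase, an enzyme of mitochondrial electron transfer. The region on chromosome 6 (36560001 to 36750000) with CDKN1A, which encodes the cell cycle inhibitor p21, and the splicing factor gene SRSF3 rose by 0.61 (0.55 to 0.66). The region with CTSD, which encodes the lysosomal protease cathepsin D, on chromosome 11 (1770001 to 1940000) also rose by 0.61 (0.50 to 0.68).

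The other regions in which targets could be placed rose by less than these. The region of PLXNB2, a semaphorin receptor gene, on chromosome 22 (50700001 to 50830000) rose by 0.48 (0.29 to 0.58). The region of TINF2, a telomere protein gene, together with RABGGTA and DHRS1 on chromosome 14 (24710001 to 24830000) also rose by 0.48 (0.38 to 0.55). The region of PLK3, which encodes a polo-like kinase, with BTBD19 and TCTEX1D4 on chromosome 1 (45220001 to 45360000) rose by 0.46 (0.36 to 0.53). On chromosome 7, the region of TTYH3 and AMZ1 (2620001 to 2760000) rose by 0.45 (0.42 to 0.48) and that of TRIP6 and UFSP1 (100430001 to 100560000) by 0.45 (0.41 to 0.49). The region of EPHA2, an ephrin receptor gene, on chromosome 1 (16410001 to 16550000) rose by 0.43 (0.30 to 0.48). The region of GDF15, a secreted stress cytokine, on chromosome 19 (18480001 to 18505000) rose by 0.37 (0.33 to 0.41), where the median change at its SON level was 0.27. The remaining 9 regions with targets, those of SFXN3, GAL3ST4, DISP2, ZBTB7B, MMP14 with LRP10, DNASE1L1, BCL9L, IP6K3 and ARVCF, rose by 0.38 to 0.44. Among the 30 regions with placed genes, the mean rise was 0.43 over 11 regions without a listed target and 0.47 over 19 regions with one, which leaves out the 12 others, with the large rises and the targets of chromosomes 2 and 3. The difference of 0.04 (95% bootstrap interval -0.01 to 0.11) did not pass the test (two-sided permutation test chosen after the data were seen, p = 0.353). With the median change at each SON level subtracted, the means were 0.24 without a target and 0.25 with one (permutation test, p = 0.902). All these regions were picked at a strict threshold on the change itself, which overstates rises and narrows any difference between the sets.

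**Figure D2:**
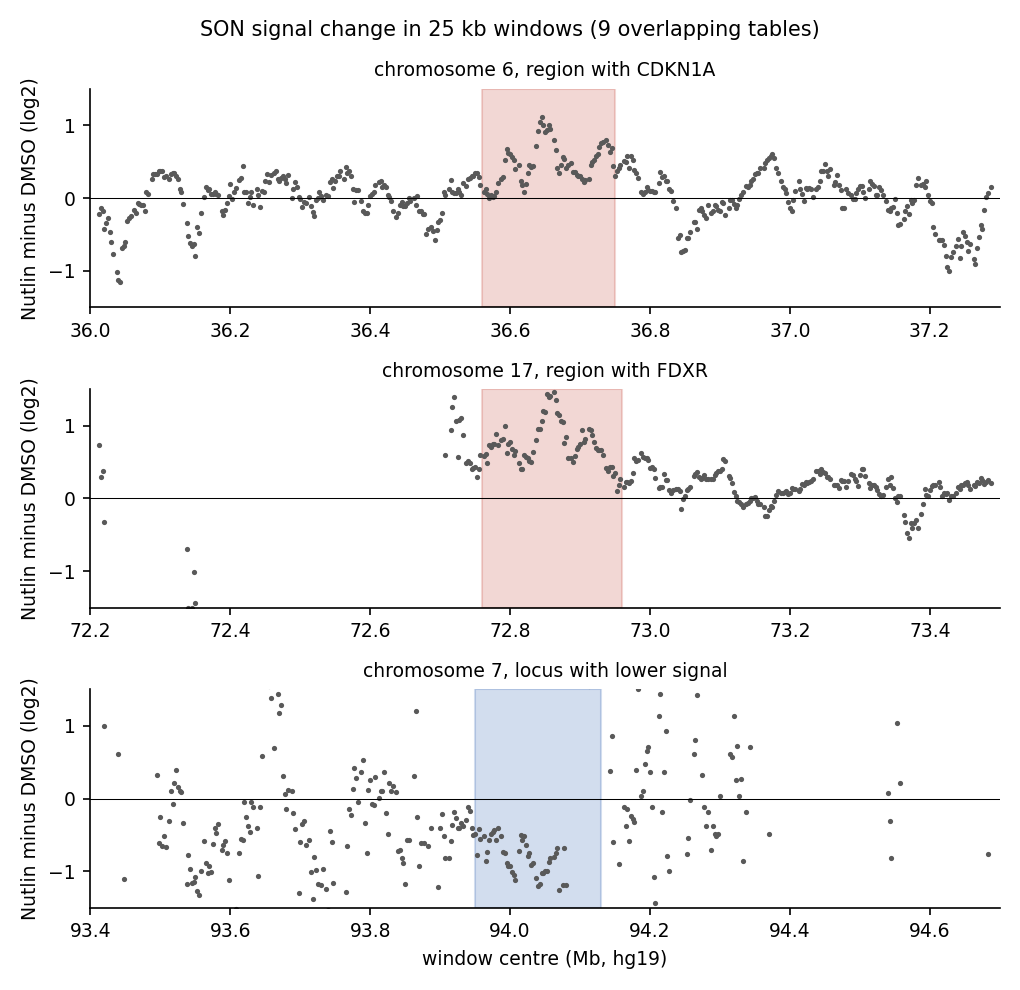
Change in SON signal (Nutlin minus DMSO, log2) in 25 kb windows of 9 overlapping tables, by window centre (Mb, hg19), around the chromosome 6 region with CDKN1A, the chromosome 17 region with FDXR and a chromosome 7 locus with lower signal. Red shading marks gained regions at FDR 0.00001 and blue shading the locus that fell; windows with no signal in a condition are left out, and 10 points on chromosome 17 and 47 on chromosome 7 lie outside the axes.

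The series asks whether p53 targets gain speckle contact. Of 1646 protein-coding targets, 296 (18.0%) were among the genes of regions gained at FDR 0.01, against 1954 of the 18324 other protein-coding genes (10.7%). The odds ratio was 1.84 (95% interval 1.61 to 2.10; Fisher's exact test, two-sided, p = 3.06e-17). Neighbouring genes share regions, so the target labels were also shifted along the gene order, which gave a mean of 185 gained targets (central 95% 155 to 216; permutation by shifts, two-sided, p = 5.03e-05, the smallest these can give). The odds ratio was 1.57 at FDR 0.1 and 3.51 at FDR 0.00001. At the latter, 23 of the 37 runs of gained genes held a target, against a mean of 9.79 for shifted labels (permutation by shifts, p = 0.000252, the smallest these can give). The authors' target list was made in the same cell line, and how it was chosen is not given in the sources used here. SON level was not compared between targets and other genes, while gained windows had a high level. The excess may therefore partly reflect which genes lie in windows that could be called.

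**Figure D3:**
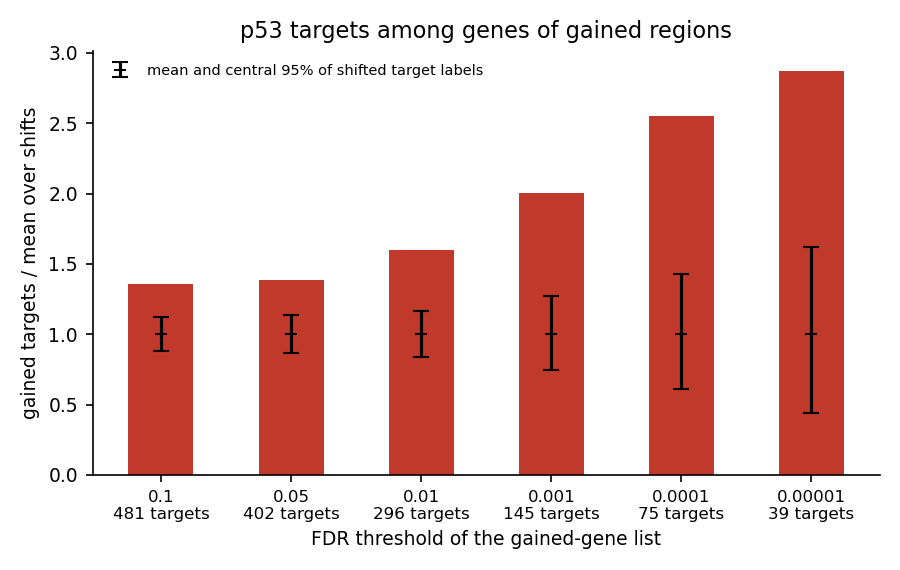
Number of p53 targets among genes of gained regions divided by the mean number for shifted target labels, at 6 FDR thresholds; black bars give the central 95% of the shifts around their mean of 1. The 6 red bars, for 481 targets at FDR 0.1 down to 39 at FDR 0.00001, all end above the black bars.

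Genes near targets were gained more often than distant ones, a pattern examined after the data were seen. The share in gained regions was 18.0% (95% Wilson interval 16.2 to 19.9) for the targets, 15.1% (13.8 to 16.5) for other genes 1 place away in the gene order, 12.1% (11.0 to 13.3) at 10 places and 9.22% (8.22 to 10.3) at 50 places. The share over all protein-coding genes was 11.3%. Targets were gained 1.18 times as often as genes drawn at most 5 places away (permutation test, two-sided, p = 0.0001, the smallest 10000 draws can give). The draws could return the target itself, which can lower this ratio. Each target was replaced independently, though neighbouring targets can share a region, so the p-value may be too small.

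**Figure D4:**
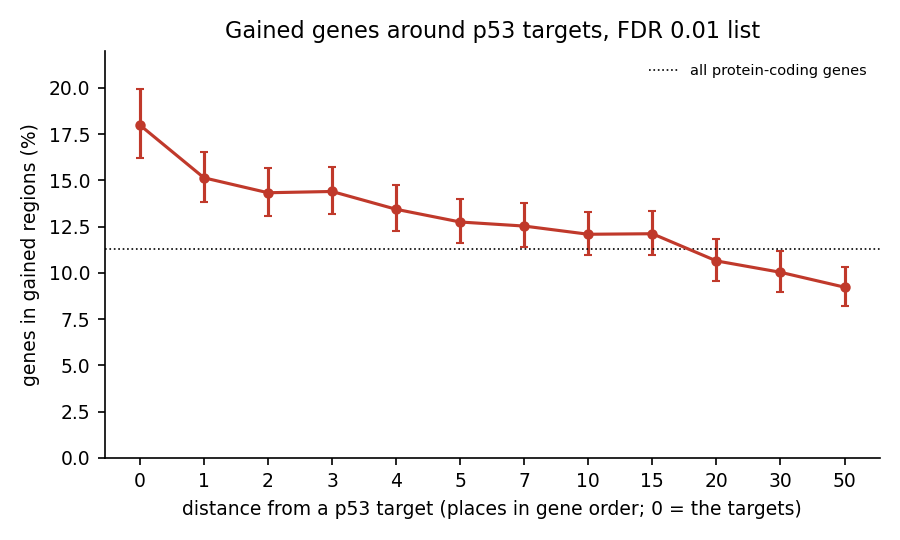
Share of genes in regions gained at FDR 0.01 (%) by distance from a p53 target in places of gene order, where 0 marks the targets; bars are 95% Wilson intervals and the dotted line is the share over all protein-coding genes, 11.3%. The share falls from 18.0% at the targets to 9.22% at 50 places.

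Groups of known p53 targets, fixed before the data were examined, were set against the genes of regions gained at FDR 0.01. On a list of 17 genes named for secreted and membrane proteins, 6 were gained, among them EPHA2, PLXNB2 and GDF15. The odds ratio against all other protein-coding genes was 4.30 (Fisher's exact test with Benjamini-Hochberg adjustment over the 17 lists, p = 0.0356). Of these 17 genes, 14 were also on the authors' target list, so the ratio may partly restate the excess of targets. With shifts along the gene order the adjusted p was 0.077 (permutation). The odds ratio was 2.55 with gained genes at FDR 0.1 (exact test, adjusted p = 0.133) and 11.9 at FDR 0.001 (exact test, adjusted p = 0.000495). Of 12 cell cycle arrest genes, 4 were gained: CDKN1A, PLK3, SFN and ZNF385A (exact test, adjusted p = 0.0961). Of 14 genes of metabolism and autophagy, 4 were gained (FDXR, SCO2, CPT1C and GPX1; exact test, adjusted p = 0.136), and of 21 apoptosis genes, 3 (BAX, BBC3 and PIDD1; exact test, adjusted p = 0.821). None of 11 genes of DNA repair and nucleotide supply and none of 10 feedback regulators was gained (exact test, adjusted p = 0.759 for each). MDM2, a feedback regulator, appeared only in the list at FDR 0.1. CCNG1, FAS, TNFRSF10B, RRM2B and ZMAT3 were in none of the 6 lists.

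Other fixed lists gave 17 gained of 80 ribosomal protein genes (odds ratio 2.13, exact test, adjusted p = 0.0387), and 0 of 390 olfactory receptor genes (exact test, adjusted p = 8.76e-20), 0 of 71 clustered histone genes (exact test, adjusted p = 0.00375) and 0 of 55 keratin genes (exact test, adjusted p = 0.0126). For ribosomal protein genes the odds ratio was 2.99 at FDR 0.1 and 1.14 at FDR 0.001, where the call was lost (exact test, adjusted p = 0.885). At FDR 0.001 histone and keratin genes also lost their calls (exact test, adjusted p = 0.218 and 0.353). Still 0 of 71 and 0 of 55 were gained there, where the share over all protein-coding genes was 4.40%. At FDR 0.1 the direction turned for keratin genes, with 13 of 55 gained (odds ratio 1.13, exact test, adjusted p = 0.841). Olfactory receptor, histone and keratin genes sit in clusters, and with shifts along the gene order no list passed, the lowest adjusted p being 0.077 (permutation). The SON level at these genes was not analysed here. A count of 0 may therefore reflect windows of low level that could not pass, and not a response to Nutlin. The lists that did not pass were heat shock genes (4 of 16, HSP90AB1 and a cluster of HSPA1A, HSPA1B and HSPA1L; exact test, adjusted p = 0.183), zinc finger ZNF genes (43 of 509, odds ratio 0.72; exact test, adjusted p = 0.0961, but odds ratio 0.429 and adjusted p = 0.0237 at FDR 0.001) and housekeeping genes (3 of 20, ACTB, POLR2A and VCP; exact test, adjusted p = 0.69). Mitotic genes repressed through p53 and DREAM (1 of 25, CDC20) and fibroblast matrix genes (1 of 26, S100A6) did not pass either (exact test, adjusted p = 0.547 for each). Nuclear speckle proteins (2 of 18, SRSF3 and U2AF2) and genes of other cell types (2 of 25, HBA1 and INS) had an adjusted p of 1 (exact test).

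Targets gained at FDR 0.01 and targets outside the list at FDR 0.1 were spread differently over the chromosomes. Chromosome 19 held 50 (16.9%) of the gained targets and 21 (1.80%) of the others (odds ratio 11.1, Fisher's exact test with Benjamini-Hochberg adjustment over chromosomes, p = 1.49e-19). Chromosomes 17 (29 against 32), 22 (19 against 14) and 11 (36 against 59) also held more of the gained targets, with adjusted p of 5.21e-06, 9.36e-06 and 0.000202 (exact test). Chromosomes 5 (1 against 89), 2 (4 against 114), 10 (3 against 59), 4 (2 against 43) and 18 (0 against 23) held fewer, with adjusted p of 4.11e-07, 5.01e-07, 0.00324, 0.0121 and 0.02 (exact test). The 2250 gained protein-coding genes, targets or not, were also unevenly spread, with 20.5% on chromosome 19, 12.8% on 17, 10.2% on 11 and 4.18% on 22, against 16.9%, 9.80%, 12.2% and 6.42% of the gained targets. Chromosome 2 held 1.73%, chromosome 10 held 1.11%, chromosome 4 held 1.07% and chromosome 5 held 0.622% of them, and chromosome 18 held 0. The authors' own lists of the 2 subsets hold 303 and 1189 genes. Neighbouring genes are not independent, so these p-values are too small.

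With the authors' scaling, loss of SON signal was rarer than gain. With the level trend removed, 17 loci lay below the trend and 22 above it in at least 1 of 27 tables. Such calls can rest on errors taken from the level. A chromosome 21 locus (9730001 to 9920000) lay below the trend in 18 tables, though the authors' FDR at 100 kb was 0.906 or more. In the authors' deposited tables, the locus found most often lay on chromosome 7 (93950001 to 94130000), where windows passed FDR 0.01 in 26 of the 27 tables with 25, 50 and 100 kb windows. In the 100 kb tables the mean difference was -0.91 log2 units (-1.16 to -0.76), which left 53.1% of the DMSO signal. A locus on chromosome 12 (46660001 to 46860000) passed in 16 tables, with -0.79 (-0.96 to -0.70) and 58.0% of the DMSO signal, and one on chromosome 17 (57830001 to 57965000) in 15 tables, with -0.49 (-0.57 to -0.37) and 71.0%. Genes at these loci were not analysed here, as gene positions of this genome build were not used here.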

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

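Tests chosen after the data were seen were the recomputed FDR over windows measured in both conditions, the trend removal, the other centres of the change, gene blocks, leaving out chromosome 19, shifts, nearby genes, the mean level, the upper 50%, the other thresholds for fixed lists, the comparison of regions with and without a target and the looser assignment. Gained 100 kb windows numbered 260 at FDR 0.01, 2656 at FDR 0.1 (of which 1754 had a condition at the lowest value), 492 at 0.05, 93 at 0.001 and 31 at 0.0001. They numbered 509 in 25 kb and 549 in 50 kb windows, where fewer windows entered the authors' adjustment. With FDR recomputed over windows measured in both conditions they numbered 153 in 25 kb, 253 in 50 kb and 275 in 100 kb windows. With the level trend removed 8 were gained and 4 lost, after a step that recovered 8.0% of simulated rises of 0.3. Centred on the highest decile of mean level 4 were gained and 24 lost, and on all measured windows 324 and 4. Lost windows numbered 5 at FDR 0.01, and 377, 19, 1 and 0 at FDR 0.1, 0.05, 0.001 and 0.0001, then 8 in 500 kb windows and 3 with the recomputed FDR. A condition was at the lowest value in 329 of the 377 and in all 8 of the 500 kb windows. Gained regions fell from 548 to 228, 96 and 42 at FDR 0.001, 0.0001 and 0.00001.

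The excess of p53 targets kept its direction and passed under all 9 alternatives run, with odds ratios from 1.57 at FDR 0.1 to 3.51 at FDR 0.00001, and 1.90 without chromosome 19. With 1 gene per 10 consecutive genes, a target wherever the 10 held any, it was 2.02. That choice leaves out the other genes beside targets, so it can raise the odds ratio. As ratios to chance, shifts gave 1.6 and nearby genes 1.18. Of the 17 fixed lists 5 passed, but 3 with gained genes at FDR 0.1, 3 at FDR 0.001 and 0 with shifts, and keratin genes turned to an odds ratio of 1.13 at FDR 0.1; the cause was not tested. The correlation of change with DMSO level, 0.018, was -0.053 in 25 kb windows, -0.0085 in 500 kb windows, -0.0050 without the lowest and highest 5% of levels, 0.112 with the mean level of both conditions and 0.497 in the upper 50%; the cause was not tested. The looser assignment of genes to regions left the difference between regions with and without a target at 0.05 (permutation p = 0.219), against 0.04.

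No paired analysis was possible because the tables give group values and not values per library. For the same reason the replicate block, leaving out each library, and scalings computed from library values were not run. Only the centre of the change was moved. Without hg19 gene positions, neither were the mean fold of targets and fixed lists with its windows, matched backgrounds, medians and spacing by 500 kb, gene starts inside regions, nor the level and length of gained against other targets. Depth per library is unknown, which limits windows of low level most.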

Other observations

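All tests of this part were chosen after the results were seen. The authors' target list has an order whose meaning is not stated. The share of targets in regions gained at FDR 0.01 was 24.2% in the first 20% of the list and 9.47% in the last. The median place was 693 for gained and 884 for other targets (permutation test, p = 1e-05, the smallest 100000 draws can give). A region on chromosome 14 (101510001 to 101560000) that holds a cluster of microRNA genes and no listed target rose by 0.50 (0.32 to 0.61).

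With the authors' scaling, SON signal rose in more windows than it fell (260 against 5), in windows where it was already high, while low levels had few calls in either direction. With the level trend removed the counts were 8 and 4. A single scaling factor on the final concentrations leaves differences between levels as they are. Such a factor is argued against for the median of the top decile of mean level lying above that of the fourth. That gap was at least 0.59 in each of the 9 tables. A scale difference before any handling of input reads was not tested, as that handling is not given in the sources used here. A single scaling factor stays open for the excess of gained windows, since the true scale between conditions is not known. Centring on the top decile (4 gained, 24 lost) cannot decide this, as that decile held 213 gained windows in the median table and loses them by construction. A level-dependent difference in enrichment between the libraries stays open for most gained windows, of which 2.87% still passed with the trend removed, and it cannot be told apart from a treatment effect on all speckle-near chromatin, since condition and libraries coincide and the step misses most rises of this size. It leaves out 5 loci above the trend in at least 14 of 27 tables. They are a pair on chromosome 2 (241200001 to 241500000 and 241580001 to 241800000) and those of FDXR, CTSD and CDKN1A. Of the 3 loci below the trend in as many tables, it leaves out those on chromosomes 7 and 17. The other, on chromosome 21, had an authors' FDR of 0.906 or more at 100 kb, so its call may rest on an error taken from the level. The strict assignment gave genes for 3 of the 5 loci above the trend, all with a p53 target. As 19 of the 30 regions with placed genes at FDR 0.00001 hold one, this sets these loci little apart.

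p53 targets were over-represented in gained regions. The gene neighbourhood is argued against as the whole cause, since targets were gained 1.18 times as often as genes at most 5 places away, though near neighbours shared much of the excess. The draws behind that ratio treated targets as independent, though neighbouring targets can share a region, which weakens the argument. A direct effect of p53 at its targets may contribute. It would predict more targets where the gain is stronger. Within the gained list at FDR 0.1, targets made up 16.5% of the 879 genes that also passed 0.001 and 9.80% of the rest (odds ratio 1.82, permutation by shifts, p = 0.000238, the smallest these can give). A stricter FDR is not a larger rise, as it also follows SON level. At FDR 0.00001 the rise was 0.47 over 19 regions with a placed target and 0.43 over 11 without (two-sided permutation test, p = 0.353). Picking those regions on the change narrows any difference. The excess of targets was seen before these tests were chosen, and no value here separates p53 itself from other features of these genes, so the hypothesis stays open. Gene length, transcription and the SON level at targets against other genes were not analysed here, and neither were cells without p53.

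A preference of gained loci for chromosome ends, beyond their SON level, was tested and was not seen. Of 132 gained loci (1 per Mb) in the first table of 100 kb windows, 31.1% lay within 5 Mb of an end, against 32.0% for windows of the same level. The ratio was 0.970 (95% Wilson interval 0.743 to 1.23, simulated binomial draws by level, p = 0.847). The windows of the same level include the gained ones, which draws the ratio towards 1.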
